A study of Mus musculus with 2 samples.

How the data were processed

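The series holds single-cell RNA libraries of the mouse abdominal aorta in a model of Kawasaki disease vasculitis: 1 library from a pool of 7 aortas of mice given LCWE and 1 from a pool of 9 aortas of mice given PBS, both taken 2 weeks after injection. Per the labels, the tissue was digested with enzymes, dead cells were removed, and 10x Genomics Single Cell 3′ libraries (V3 chemistry) were made and processed with Cell Ranger 3.0.2 against mm10. The deposited values are raw UMI counts per gene and cell, with no normalization. The authors also deposited a table of the cells with the percent of each cell's UMIs in the 13 mitochondrial genes, which was recomputed from the counts. The deposited table further gives a doublet score per cell from a caller that it does not name, and the score was not used. The authors' calls of dead cells and doublets are negative for all listed cells, so cells that met those calls are absent. Empty droplets and unlisted barcodes are not in the files.

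Both libraries list 27998 genes, and the 10477 cells of the joint matrix were checked against the tables of the single libraries: of 293335046 entries, 0 differ. Totals and gene numbers per cell equal the deposited ones in 10477 cells. The lowest UMI total of a cell is 1613 in the LCWE library and 1671 in the PBS library, and the highest mitochondrial share 15.0% in both after rounding. The median UMIs per cell were 11494 and 6215 in fibroblasts (LCWE, then PBS), 9201 and 6284 in endothelial cells, 8547 and 11880.0 in smooth muscle cells, 3986 and 4374 in T, NK and innate lymphoid cells, and 19942 in the transitional class.

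Cells kept the names the authors gave them, in 9 broad and 25 fine classes. The comparisons, the gene lists, the cell type markers and the rule for named genes were fixed before the data were examined. For shares, the cells of a class were divided by the cells of the library, with exact Clopper-Pearson intervals. For expression, UMIs were summed over the cells of a class and library and divided by the total UMIs of these cells (CPM), with exact Poisson intervals, and ratios of LCWE over PBS carry exact conditional binomial intervals. For ranks, log2 ratios and list medians, a sum under 3 UMIs over the class was raised to a floor of 3. Fold ratios are given as counted with their interval where the lower library had 1 UMI or more, and against the floor, written as "at least", where it had 0, and shares of 0 cells against a floor of 3 cells. Classes with at least 50.0 cells in both libraries were compared: fibroblasts, endothelial cells, smooth muscle cells, and T, NK and innate lymphoid cells.

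Genes were named by this rule. In classes with at least 100 cells in both libraries, which were fibroblasts and endothelial cells, the 10 genes with the highest and the 10 with the lowest ratio were taken. They needed at least 50 UMIs in the library where they were higher, an interval wholly beyond 1.5-fold, no cell with over 20% of those UMIs, and at least 5% of the CPM of the class where the gene was most abundant. Mitochondrial, ribosomal, haemoglobin, antigen receptor and sex-linked genes and markers of other cell types were excluded, and genes without an approved name were ranked and need not be named. From each gene list came up to 4 members with the most UMIs, those at least 2-fold different first, and from the inflammasome list all members. Of the list members that the rule names, the text gives a part, picked after their values were seen. Col4a3 was named in both classes. Markers and genes outside the rule (Emb beside lymphocytes, for example) are given as context.

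Gene lists were written by hand for contractile genes, smooth muscle switching, matrix, matrix proteases and inhibitors, inflammasome and IL-1, chemokines, cytokines, NF-κB targets, type I interferon response, interferon gamma response, class I and class II antigen presentation, endothelial activation, endothelial quiescence, complement, glycolysis and hypoxia, TGF-β response, cycling, dissociation, mitochondrial and haemoglobin genes, and for inflammatory myeloid cells and cytotoxic, naive, regulatory and exhausted T cells. A member counted as measured with at least 20 UMIs in both libraries together, and members with fewer than 3 UMIs in a library entered the median at their bound against the floor. Ccn1 and Ccn2 are listed in the files as Cyr61 and Ctgf, and Trac was not matched. The share of a gene's UMIs that each class held was computed with Clopper-Pearson intervals for IL-1, chemokine and cytokine genes. UMIs per lymphocyte served as the measure of free RNA. Gene positions come from GENCODE vM21 (GRCm38), where 312 of 314 symbols were matched.

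The method was tested on simulated Poisson counts with the depth of each class, without variation between cells or animals and without free RNA. The changed genes were drawn from those with expected sums of at least 50 UMIs in both libraries. Recovery is thus shown for abundant genes alone. Of 100 genes made 2-fold different, 78% were recovered in fibroblasts, 71% in endothelial cells, 85% in smooth muscle cells and 63% in T, NK and innate lymphoid cells, and of 100 genes made 4-fold different 99%, 100%, 100% and 100%. The intervals covered the true ratio for 95.7%, 96.2%, 97.0% and 97.2% of genes. They assume Poisson counts too, so this coverage checks the calculation and not the spread of real data.

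The alternatives fixed in advance were a filter of at least 1000 UMIs and at most 10% mitochondrial UMIs, doublets called by Scrublet left out (expected rate 6%), clusters made here in place of the authors' classes, TMM factors, the mean over cells of UMIs per 10000, member limits of 5 and 100 UMIs, members under 5% of the top class left out, cells thinned to 1500 UMIs, and the composition of the PBS library held fixed. Chosen after seeing the data were blood endothelial cells alone, clusters shared by both libraries (at least 10 cells of the class in each, lymphatic cells left out), smooth muscle cells with the transitional class, and filters on the shares of a gene's UMIs and on the transitional class. Clusters used 2000 variable genes, 30 components, 15 neighbours and Leiden resolution 0.5 or 1.0, seed 0. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, scikit-image 0.26.0, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16. Cells were not used as replicates, and no class with fewer than 50 cells in a library was compared for expression.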

Results

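Single-cell transcriptomes were collected from the abdominal aorta of wild-type mice (C57BL/6J) injected in the peritoneum 2 weeks earlier with Lactobacillus casei cell wall extract (LCWE) or with phosphate-buffered saline (PBS). LCWE is a bacterial cell wall preparation that causes a vasculitis of the coronary arteries and abdominal aorta in mice and serves as a model of Kawasaki disease, a childhood vasculitis. The aortas were dissociated with enzymes, dead cells were removed, and 3′ droplet libraries were made from 1 pool of 7 LCWE aortas and 1 pool of 9 PBS aortas. The deposited counts held 5091 LCWE cells with 42275754 unique molecular identifiers (UMIs, each counting 1 captured transcript) and 5386 PBS cells with 62600808 UMIs. The median cell had 5508 UMIs, 1848 genes and 4.3% mitochondrial UMIs in the LCWE library, against 11252.5 UMIs, 3270.0 genes and 6.68% in the PBS library. Each group is 1 pooled library with no replicate, so animals within a group cannot be compared, no test was made, and the brackets after each value hold 95% intervals that cover counting error only.

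What cells did the inflamed abdominal aorta hold? Smooth muscle cells, the main cell type of the arterial wall, made up 4141 of 5386 cells, 76.9% (75.7 to 78), of the PBS library and 93 of 5091 cells, 1.83% (1.48 to 2.23), of the LCWE library, a share 42.1-fold (34.3 to 52.3) lower in the LCWE pool. Leukocytes made up 3534 of 5091 cells, 69.4% (68.1 to 70.7), of the LCWE library and 116 of 5386 cells, 2.15% (1.78 to 2.58), of the PBS library. T, natural killer (NK) and innate lymphoid cells were the most numerous class of the LCWE library, with 2198 of 5091 cells, 43.2% (41.8 to 44.5), against 75 of 5386 cells, 1.39% (1.1 to 1.74). A class that the authors named transitional between smooth muscle and fibroblast held 283 of 5091 cells, 5.56% (4.95 to 6.22), in the LCWE library and 0 of 5386 cells, which allows a share of up to 0.0557% by a floor of 3 cells and 0.0685% by the exact interval, in the PBS library. Its share was at least 99.8-fold higher against the floor, with an exact lower limit of 80.6-fold.

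Monocytes, macrophages and dendritic cells were 17.8% (16.8 to 18.9) of the LCWE cells and 0.334% (0.198 to 0.528) of the PBS cells, and the class of other myeloid cells, which holds granulocytes, was 4.01% (3.48 to 4.58) and 0.111% (0.0409 to 0.242). B cells were 4.4% (3.85 to 5.0) and 0.316% (0.184 to 0.505). Of all cells, fibroblasts were 16% (15 to 17) and 16.1% (15.1 to 17.1), and endothelial cells 6.42% (5.76 to 7.13) and 4.57% (4.03 to 5.16). Of the non-immune cells alone, which hold the smooth muscle cells, fibroblasts were 52.2% (49.7 to 54.7) and 16.5% (15.5 to 17.5), 3.17-fold (2.88 to 3.49) higher in the LCWE pool. Endothelial cells were 21% (19 to 23.1) and 4.67% (4.11 to 5.27) of them, 4.5-fold (3.8 to 5.33) higher. Blood endothelial cells were 4.7% (4.13 to 5.31) and 4.03% (3.52 to 4.59) of all cells, with overlapping intervals, while lymphatic endothelial cells were 1.73% (1.39 to 2.12) and 0.538% (0.361 to 0.772) of all cells, 3.21-fold (2.09 to 5.07) higher in the LCWE pool. Of the endothelial cells alone, lymphatic cells were 26.9% (22.2 to 32.1) and 11.8% (8.04 to 16.5), 2.28-fold (1.49 to 3.6) higher, and blood endothelial cells 73.1% (67.9 to 77.8) and 88.2% (83.5 to 92). Proliferating stromal cells numbered 41 in the LCWE library and 15 in the PBS library. With cells over 10% mitochondrial UMIs left out, the LCWE share of smooth muscle cells was 1.25%.

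**Figure D1:**
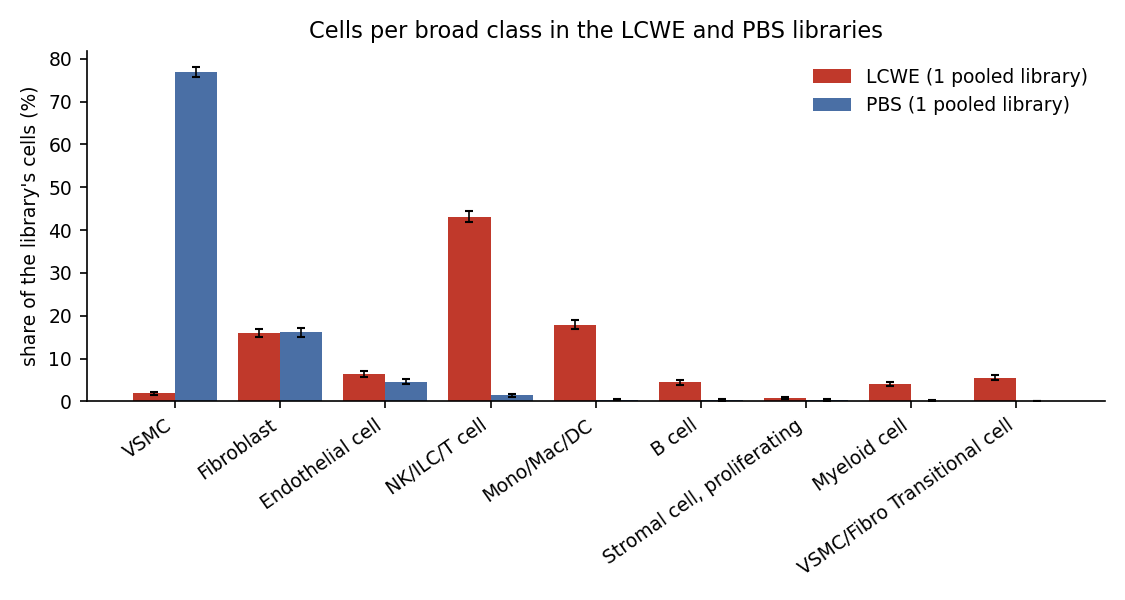
Share of each library's cells (y axis, percent) in the 9 broad classes named by the authors (x axis), with 1 bar for the LCWE pool and 1 for the PBS pool. Error bars are exact 95% Clopper-Pearson intervals and cover counting error only. Smooth muscle cells (VSMC) made up 76.9% of the PBS library and 1.83% of the LCWE library, and NK, innate lymphoid and T cells 43.2% of the LCWE library.

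Among the lymphocytes of the LCWE library, several fine classes were of like size: naive CD4 T cells held 6.33% (5.67 to 7.03) of all cells, cells named NKT 6.25% (5.6 to 6.95), regulatory and activated CD4 T cells 5.78% (5.15 to 6.45), activated CD8 T cells 5.78% (5.15 to 6.45) and NK cells 5.52% (4.91 to 6.18). Proliferating T cells, at 1.28% (0.987 to 1.62), and γδ T cells, at 1.06% (0.798 to 1.38), were smaller classes. Naive CD8 T cells were 5.5% (4.89 to 6.16) of the LCWE cells and 1 cell of the PBS library, and the cells named NKT were absent among the 5386 PBS cells. Mono1 monocytes and Mac1 macrophages were the largest mononuclear phagocyte classes, at 5.52% (4.91 to 6.18) and 5.54% (4.93 to 6.2), followed by DC2 dendritic cells at 3.83% (3.32 to 4.39). Plasmacytoid dendritic cells were 0.923% (0.679 to 1.23) of the LCWE library and 0 of 5386 PBS cells. Cells that the authors named eosinophils were 2.79% (2.35 to 3.28), and neutrophils were 1.22% (0.935 to 1.56).

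The NLRP3 inflammasome is a protein complex that activates caspase-1, which matures interleukin-1 (IL-1), a cytokine that drives acute inflammation. Which cells held their transcripts? Il1b (chromosome 2, 129364570 to 129371139, GRCm38), which encodes IL-1β, was at 732 against 6.74 CPM, 109-fold (98.7 to 119.8) higher in the LCWE library as a whole (CPM are UMI counts scaled to the total of the library or, below, of the cell class). Monocytes, macrophages and dendritic cells held 61.2% (60.7 to 61.8) of the 30954 Il1b UMIs of the LCWE library, and the other myeloid cells, which were 4.01% of the cells, held 29.3% (28.8 to 29.8). Per cell, Il1b was highest in the cells named eosinophils, at 50.9 UMIs, against 29.5 in the cells named neutrophils, 28.8 in DC2 dendritic cells, 20.4 in Mono1 monocytes and 19.7 in Mac1 macrophages. In T, NK and innate lymphoid cells, where free RNA from broken cells may set a background, it was 0.416 UMIs per cell, against 1.36 in LCWE fibroblasts.

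Nlrp3 (chromosome 11, 59541568 to 59566956), the inflammasome sensor, was at 73.6 against 0.751 CPM, 98-fold (73.5 to 134) higher in the LCWE library. Its 3110 LCWE UMIs lay in the cells named eosinophils with 34.2% (32.5 to 35.9) and in Mac1 macrophages with 22.7% (21.2 to 24.2), and by broad class 45.4% (43.6 to 47.2) lay in monocytes, macrophages and dendritic cells and 42.7% (41 to 44.5) in the other myeloid cells. Il1a, which encodes IL-1α, had 359 UMIs, 62.1% (56.9 to 67.2) of them in the other myeloid cells. Il1rn, the gene of the IL-1 receptor antagonist, was at 74.4 against 0.799 CPM, 93.1-fold (70.5 to 126) higher, with 57.6% (55.9 to 59.4) of its UMIs in monocytes, macrophages and dendritic cells. The receptor lay elsewhere. Il1r1 (chromosome 1, 40225080 to 40317257), the signalling receptor for IL-1, had 72.8% (71 to 74.5) of its 2477 LCWE UMIs in fibroblasts and 13% (11.7 to 14.4) in the transitional class. In the PBS library, where smooth muscle cells were most numerous, they held 80.9% (79.1 to 82.7) of its 1821 UMIs. Per PBS cell it was at 0.356 UMIs in smooth muscle cells and 0.354 in fibroblasts. Scaled to the UMIs of each class, which were more per smooth muscle cell, it was at 27.6 and 50.5 CPM. Part of the library-wide difference went with the cell composition: with each class weighted by its share of UMIs in the PBS library, the log2 ratio was 4.24 for Il1b, against 6.76 in the library as collected, and 4.26 for Nlrp3, against 6.61. Smooth muscle cells held 53468481 of the 62600808 PBS UMIs, so the weighted values depend mostly on that class. Its 93 LCWE cells had 2.48 UMIs of neutrophil markers per cell, against 0.0362 per PBS cell of the class. Transcripts caught from leukocytes are therefore not excluded as the source of the weighted ratios, which do not show higher expression within classes. Leukocyte classes had too few PBS cells for a comparison. Il1b was at 20.9 (LCWE) and 21.7 (PBS, 18 cells) UMIs per cell in monocytes, macrophages and dendritic cells. In the other myeloid cells it was at 44.4 and 2.67 (PBS, 6 cells). Nlrp1b, with 28 and 4 UMIs, had a log2 ratio of 3.37 as collected and -2.43 with the PBS composition.

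**Figure D2:**
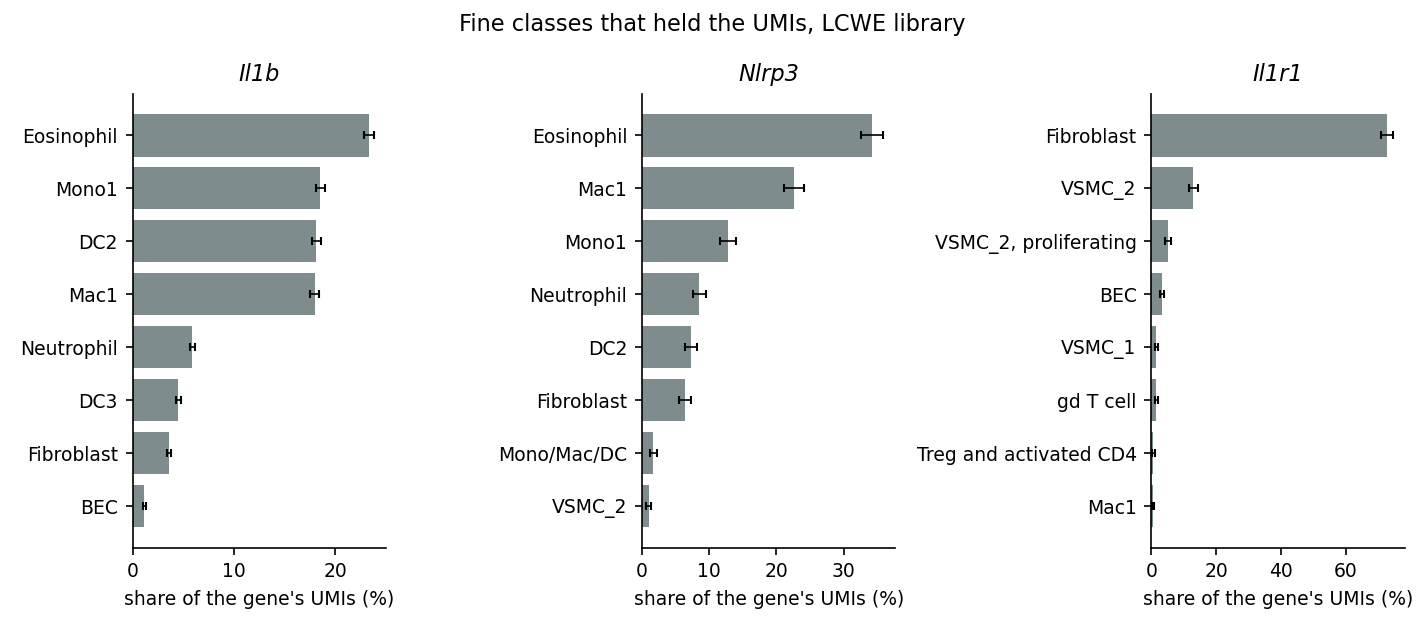
Share of the LCWE library's UMIs of Il1b, Nlrp3 and Il1r1 (x axis, percent of the gene's UMIs) in the 8 fine classes with the highest share (y axis, class names given by the authors; VSMC_2 is the transitional class). Error bars are exact 95% Clopper-Pearson intervals. The ligand and the sensor lay in myeloid classes, and 72.8% of the receptor's UMIs lay in fibroblasts. In the PBS library, which is not drawn, smooth muscle cells held 80.9% of the receptor's UMIs.

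Chemokine transcripts of the LCWE library were split between stroma and leukocytes. Fibroblasts held 60.1% (59 to 61.2) of the UMIs of Ccl2 and 75.5% (74.6 to 76.5) of those of Ccl7, chemokines that attract monocytes. They also held 61.9% (61.2 to 62.6) for Cxcl1, which attracts neutrophils, 66.4% (65.8 to 67) for Cxcl12, 96.1% (95.2 to 96.8) for the eosinophil chemokine Ccl11 and 95.1% (94.1 to 96) for the B cell chemokine Cxcl13. The other myeloid cells held 45% (44.6 to 45.5) of the UMIs of Cxcl2 and 58.2% (56.7 to 59.6) of those of Ccl3, and T, NK and innate lymphoid cells held 87.1% (86.8 to 87.4) for Ccl5. The transitional class, 5.56% of the cells, held 67.5% (64 to 70.9) of the UMIs of Cxcl5 and 66.6% (61.8 to 71.1) of those of Lif, a cytokine of the IL-6 family. Fibroblasts held 70.2% (68.7 to 71.8) of the Il6 UMIs and 88.5% (87.7 to 89.3) of those of Il33, an alarmin of the IL-1 family, while monocytes, macrophages and dendritic cells held 40.5% (38.1 to 42.9) for Tnf and 60.5% (58.4 to 62.6) for Osm.

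How did the stromal classes that both libraries hold differ? Over all fibroblasts, complement, chemokine and interferon-response genes were higher in the LCWE pool, while contractile genes were lower. In the fibroblast clusters that both libraries shared, described below, complement (median log2 ratio 1.07) and contractile genes (-1.14) kept their direction. There the chemokine (0.14), type I interferon (0.04) and interferon gamma (0.02) lists were nearly alike in both pools. Saa3 (chromosome 7, 46711998 to 46715700), an acute-phase serum amyloid gene, had 15585 against 1 UMIs, or 1561 against 0.164 CPM, a ratio of 9497-fold (1704 to 375155). Also far higher were Lcn2, which encodes the iron-binding lipocalin-2, with 2991 against 4 UMIs and 456-fold (178 to 1674), Lrg1 with 655 against 1 UMIs and 399-fold (71.4 to 15789.6), and Chl1, a cell adhesion gene, which was at least 546-fold higher with 2688 against 0 UMIs. The other genes with the largest ratios were Kng2 at 205-fold (56.6 to 1699), Wfdc17 at 139-fold (38.2 to 1148), Crocc2 at 132-fold (36.2 to 1090.0), Nfasc at 114-fold (31.4 to 947), Oas2 at 112-fold (30.8 to 929) and Emb at 88.3-fold (46.4 to 194). Emb was also at 2.34 UMIs per LCWE lymphocyte, above its 1.6 UMIs per LCWE fibroblast. The genes with the largest ratios in the other direction were Lgi1, 63.2-fold (16.9 to 531) lower, Lamc3, 40.5-fold (25.6 to 67.9), Angptl7, 39-fold (27 to 58.2), Rbp4, the retinol carrier, 30.5-fold (27.4 to 34), Lrrn1, 29-fold (9.4 to 145), Col4a3, 26.5-fold (18.1 to 40.3), Nalcn, 21.1-fold (9.25 to 59.2), and Dner, 19.9-fold (11.6 to 37.2), and Heyl, a target of Notch signalling, with 21 against 256 UMIs.

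Many of these differences lay in a fibroblast cluster found in the LCWE library. When the cells of both libraries were clustered together, 615 of the 813 LCWE fibroblasts lay in a cluster with 0 of the 868 PBS fibroblasts. The genes that set this cluster apart from all other cells included Chl1 and Crocc2, named above. Wt1, which is on the mesothelial marker list used here, was among them too. Ratios over all fibroblasts thus do not separate a change within like cells from a different kind of cell in the LCWE pool, which was not tested. The clusters that both libraries shared held 197 LCWE fibroblasts and 867 PBS fibroblasts. The median LCWE cell of the LCWE-only cluster had 13804.0 UMIs, and the median LCWE fibroblast of the shared clusters 6301 UMIs. The lists are therefore given for all fibroblasts and for the shared clusters alone, a comparison added after the data were seen.

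Of the complement list, 8 of 11 measured members were at least 2-fold higher in LCWE fibroblasts, with a median log2 ratio of 2.14, and the shared clusters gave 1.07. The list includes C1qa, C1qb and C1qc, which are macrophage markers. Macrophage markers had 1.26 UMIs per LCWE fibroblast against 0.156 per PBS fibroblast, so transcripts caught from macrophages are not excluded for these members. C3 (chromosome 17, 57203970 to 57228136), the central complement component, was at 6971 against 1580.0 CPM, 4.41-fold (4.32 to 4.51) higher. C4b was 15.1-fold (13.9 to 16.3) higher, and the C1 proteases C1s1 and C1ra were 2.49-fold (2.38 to 2.6) and 2.15-fold (2.03 to 2.29) higher. Of the chemokine list, 10 of 17 members were at least 2-fold higher, with a median of 2.05, against 0.14 in the shared clusters. Cxcl12 was 4.13-fold (3.94 to 4.33) higher, Cxcl2 7.24-fold (6.5 to 8.08), Cxcl13 5.39-fold (4.67 to 6.24) and Cxcl14 8.51-fold (6.88 to 10.6). In the shared clusters Cxcl14 was lower, with a log2 ratio of -0.43. Of the cytokine list, with a median of 0.31 over 8 members, Il33 was 5.91-fold (5.43 to 6.45) higher, while Il6 was at 241 against 365 CPM. The list of NF-κB targets had a median of -0.15 over 10 members, with 1 at least 2-fold higher.

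Of the type I interferon response list, 11 of 12 members were at least 2-fold higher in LCWE fibroblasts, with a median of 2.09. Bst2 was 2.57-fold (2.38 to 2.79) higher, Isg15 3.78-fold (3.37 to 4.25), Ifit1 4.78-fold (4.16 to 5.51) and Irf7, the transcription factor of this response, 4.96-fold (4.2 to 5.88). In the shared clusters the median of the list was 0.04 over 8 members, and Ifit1 and Irf7 had log2 ratios of -0.38 and -0.41. Of the interferon gamma response list, 5 of 10 members were at least 2-fold higher and 1 lower, with a median of 1.10, against 0.02 in the shared clusters. Gbp3 was 3.07-fold (2.41 to 3.95) higher and Cxcl9 9.28-fold (6.03 to 15), while Irf1 was 2.06-fold (1.9 to 2.24) lower. With clusters made here in place of the authors' classes, Gbp3 was alike in both pools, with a log2 ratio of -0.00. The LCWE-only cluster took no name there, so that comparison is nearly the one of the shared clusters. The class I antigen presentation list had a median of 0.96 over 8 members, with B2m 1.94-fold (1.87 to 2.01) higher and Psmb8 2.2-fold (1.91 to 2.54) higher, and 0.62 in the shared clusters. The class II list had a median of 5.58 over 6 members. Cd74 was at 309 against 2.63 CPM and H2-Aa at 122 against 1.97 CPM, and class II transcripts were found in LCWE lymphocytes too, with 3.84 class II UMIs per cell against 8.13 in LCWE fibroblasts.

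Of the inflammasome and IL-1 list, 8 of 12 measured members were at least 2-fold higher in LCWE fibroblasts, with a median of 1.69. Il1r1 was at 181 against 50.5 CPM, 3.58-fold (3.17 to 4.05) higher. Il1r2, a decoy receptor, was 10.4-fold (6.29 to 18.4) higher and Il1rn 85.9-fold (15.2 to 3418). Il1b was at least 225-fold higher and Nlrp3 at least 40.2-fold, with 1108 against 0 UMIs and 198 against 0 UMIs. Il1b, Nlrp3, Il1r2 and Il1rn are abundant in the myeloid cells of the same library, and the neutrophil marker list was 5.55 higher on the log2 scale in the same fibroblasts. Il1r2 was at 27.3 CPM in LCWE fibroblasts against 932.5 in the other myeloid cells, and Il1rn at 14.1 against 712. Transcripts caught from myeloid cells are not excluded for these genes, which are part of the count of 8 members. Aim2, at 6.4-fold (1.56 to 56.3), Casp1, at 2.91-fold (1.58 to 5.76), and Pycard, at 2.32-fold (1.91 to 2.84), were no more abundant per fibroblast than the level found in lymphocytes or only slightly so. That level cannot measure free RNA for these genes, since PBS lymphocytes held them too. Per PBS lymphocyte and PBS fibroblast, Pycard had 1.52 and 0.151 UMIs, Casp1 0.133 and 0.015, and Aim2 0.133 and 0.0023. Gsdmd was at 1.64-fold (1.26 to 2.15) and Casp4 at 1.04-fold (0.905 to 1.2), with a log2 ratio of -0.06 for Gsdmd in cells thinned to an equal depth, while Il18 was 1.38-fold (1.1 to 1.72) lower and Il1rap 1.79-fold (1.4 to 2.29) lower.

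Matrix genes moved apart in fibroblasts. The matrix list had a median of -0.43 over 16 members, with 5 at least 2-fold lower and 1 higher: elastin, Eln, was 5.27-fold (5.14 to 5.41) lower, Col6a1 2.13-fold (2.06 to 2.19) and Col6a3 2.44-fold (2.35 to 2.53) lower, while periostin, Postn, was 2.83-fold (2.72 to 2.95) higher. The list of matrix proteases and their inhibitors had a median of 0.96 over 11 members, with Mmp3 2.08-fold (1.98 to 2.17) higher, Mmp14 2.89-fold (2.66 to 3.15) higher and Timp1 3.2-fold (3.01 to 3.42) higher. The TGF-β response list had a median of -0.44 over 9 members, 4 of them at least 2-fold lower, with Tgfbi 4.36-fold (4.14 to 4.59) lower and Ctgf 7.0-fold (6.44 to 7.62) lower. The list of genes linked to smooth muscle phenotype switching had a median of 0.81 over 13 members, with Ly6a 2.43-fold (2.37 to 2.49) and Runx1 8.46-fold (7.1 to 10.2) higher and Mgp, an inhibitor of calcification, 3.72-fold (3.65 to 3.79) lower. The glycolysis and hypoxia list had a median of 0.41 over 10 members, with Hif1a 3.28-fold (2.95 to 3.65) higher, and the cycling list 1.05 over 9. The contractile list was lower with a median of -2.71 over 13 members, with Acta2 8.26-fold (7.33 to 9.32) lower and Tagln 9.29-fold (7.76 to 11.2) lower. Free contractile RNA was also less abundant in the LCWE library, at 0.506 UMIs per lymphocyte against 4.69 in the PBS library. Genes that dissociation induces had a median of -0.80 over 14 members, with Fos 2.03-fold (2.0 to 2.07) lower and Junb 2.36-fold (2.31 to 2.42) lower. Mitochondrial genes had a median of 0.00, and haemoglobin transcripts a median of 4.32, with Hbb-bs at 809.9 against 39.8 CPM.

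The other fibroblast lists had these medians in the shared clusters: inflammasome and IL-1 0.81, cytokines -0.17, NF-κB targets -0.38, class II 4.16, matrix -0.40, matrix proteases and inhibitors 0.22, TGF-β response -0.64 and switching 0.46. Contractile genes had -1.14 there, glycolysis and hypoxia 0.15, cycling 0.63, dissociation -0.65, mitochondrial 0.14 and haemoglobin 4.82.

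**Figure D3:**
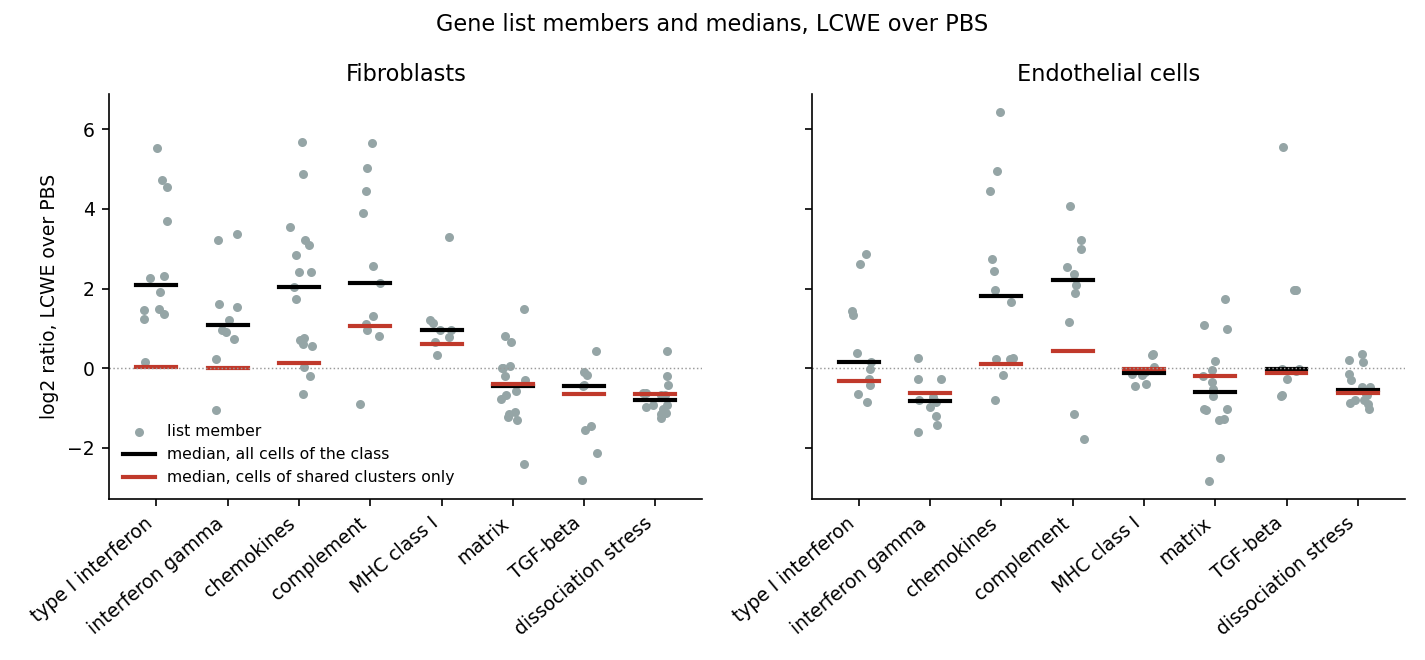
Log2 ratio of LCWE over PBS (y axis) for 8 gene lists (x axis) in fibroblasts and endothelial cells. Each grey point is 1 list member with at least 20 UMIs, the black line is the median over all cells of the class, and the red line is the median when only clusters shared by both libraries are kept. In fibroblasts the type I interferon median was 2.09 in all cells and 0.04 in the shared clusters, while the complement median was 2.14 and 1.07.

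Over all endothelial cells, complement and chemokine genes were higher in the LCWE pool, and interferon gamma response genes were lower. In the endothelial cluster shared by both libraries, described below, the chemokine list had a median log2 ratio of only 0.12. The genes with the largest ratios include a marker of the venules through which lymphocytes leave the blood. Glycam1 (chromosome 15, 103562759 to 103565081), a mucin ligand of L-selectin known from high endothelial venules, was at least 76-fold higher in the LCWE pool with 430 against 0 UMIs, Aplnr, the apelin receptor, at least 52.9-fold with 299 against 0 UMIs, and Dclk1 at least 46.2-fold with 261 against 0 UMIs. Mdk, the growth factor midkine, was 56.5-fold (24 to 175) higher, Ltbp2 47.2-fold (23.8 to 109.8), Fam167b 116-fold (20.5 to 4589), Csf2rb 47.2-fold (12.9 to 393), Vwa1 39.97-fold (18.2 to 109.5), Serpina3n 31.5-fold (15.2 to 78.9) and Tmem252 31.1-fold (13.2 to 96.5). Of the genes with the largest ratios in the other direction, the type IV collagen genes Col4a3 and Col4a4 were 49.6-fold (22.3 to 137) and 35.9-fold (23.4 to 57.9) lower, the adrenergic receptor gene Adra2a 21-fold (14.9 to 30.4), Adh1 16.6-fold (10.7 to 27.1), Degs2 15.5-fold (7.74 to 35.2), Perp 13.5-fold (7.17 to 28.2), and the kallikrein genes Klk10 and Klk11 13.9-fold (11.8 to 16.4) and 13.2-fold (8.02 to 23). Pla2g5, a phospholipase gene, had 5 against 84 UMIs. As in fibroblasts, 134 of 239 LCWE blood endothelial cells lay in a cluster with 1 of 217 PBS cells, and 103 lay in the cluster that held 215 of the PBS cells. Glycam1, Aplnr, Fam167b and Tmem252 were among the genes that set the first cluster apart from all other cells. Klk10, Klk11, Degs2 and Adra2a were among those of the cluster with most PBS cells. The ratios of these genes thus follow which cluster each library held, and a change within like cells was not separated from that. Values for shared clusters of endothelial cells leave out lymphatic cells.

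Of the complement list, 8 of 10 members were at least 2-fold higher in LCWE endothelial cells and 2 lower, with a median of 2.22 in all cells. In the shared clusters the median was 0.44, over only 4 members. C1q genes, which are macrophage markers, are part of this list. Serping1 was 2.26-fold (1.89 to 2.72) higher and C3 16.8-fold (9.53 to 32.9) higher. Chemokines had a median of 1.82 over 12 members and 0.12 over 6 in the shared clusters, with Cxcl12 5.44-fold (4.57 to 6.52) and Cxcl2 3.93-fold (3.25 to 4.78) higher in all cells. The cytokine list had a median of 2.09 over 7 members, 4 at least 2-fold higher and 1 lower, with Il6 6.59-fold (3.07 to 16.9) higher, and NF-κB targets 0.38 over 10. The interferon gamma response list was lower, with a median of -0.81 over 10 members and -0.61 in the shared clusters: Irf1 was 2.31-fold (2.0 to 2.67) lower, Igtp 2.67-fold (2.04 to 3.53), Gbp5 3.01-fold (2.06 to 4.43) and Iigp1 1.96-fold (1.65 to 2.32). The type I interferon list had a median of 0.16 over 11 members, 4 of them at least 2-fold higher, among them Ifi44 at 6.19-fold (3.43 to 12.3), Irf7 at 2.73-fold (1.72 to 4.52) and Rsad2 at 7.25-fold (3.19 to 20.3). Class I antigen presentation had a median of -0.12 over 8 members. The class II list was higher, with a median of 3.25 over 6 members, Cd74 at 445 against 29.3 CPM and H2-Aa at 175 against 14.2 CPM, and 11 class II UMIs per LCWE endothelial cell against 3.84 per LCWE lymphocyte.

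The endothelial activation list had a median of 0.14 over 10 members, 3 of them at least 2-fold higher: Plvap, which forms the diaphragms of fenestrae, 2.99-fold (2.7 to 3.31), Lrg1 10.7-fold (8.87 to 12.9) and Ackr1, a chemokine-binding receptor of venules, at least 14.9-fold with 84 against 0 UMIs. Vwf was at 969 against 1031 CPM, and had a log2 ratio of 0.11 in the shared clusters. The quiescence list had a median of -0.16 over 9 members and 0.47 in the shared clusters, with Dll4 2.32-fold (1.74 to 3.15) and Hey1 2.42-fold (1.66 to 3.62) higher and Klf2 1.22-fold (1.17 to 1.27) lower. Klf2 was higher in the shared clusters and in cells thinned to an equal depth, with log2 ratios of 0.27 and 0.09. The inflammasome and IL-1 list had a median of 0.49 over 11 members, with Il1b 22.4-fold (12.1 to 47) higher, Casp1 2.27-fold (1.61 to 3.23) lower and Il1r1 at 1.4-fold (0.918 to 2.2). Leukocyte transcripts were higher in the same cells: neutrophil markers had 2.16 against 0.0529 UMIs per cell, T cell markers 1.08 against 0.061 and macrophage markers 0.798 against 0.134. The matrix list had a median of -0.60 over 16 members, with Col5a2 2.14-fold (1.98 to 2.32) higher and Bgn 2.04-fold (1.98 to 2.1) lower, proteases and inhibitors 1.47 over 8 with Mmp14 5.79-fold (4.4 to 7.75) higher, and the switching list 1.01 over 12 with Thbs1 2.27-fold (2.09 to 2.45) and Col8a1 3.69-fold (3.28 to 4.15) higher. The matrix median turned positive in blood endothelial cells alone. In the shared clusters Thbs1 was lower, with a log2 ratio of -2.76. The TGF-β response list had a median of -0.02 over 9 members, with Tgfbi 3.91-fold (3.27 to 4.7) higher, and the glycolysis and hypoxia list 0.37 over 10 with Hif1a 3.24-fold (2.7 to 3.92) higher. Cycling genes had a median of 1.66 over 9 members and 0.33 over 3 in the shared clusters. Dissociation genes had -0.55 over 14, mitochondrial genes 0.01 over 8, and haemoglobin 4.94, with Hbb-bs at 2658 against 58.6 CPM. The other endothelial lists had these medians in the shared clusters: NF-κB targets 0.12, type I interferon -0.32, class I -0.02, class II 2.98, activation 0.11, inflammasome and IL-1 0.27, matrix -0.19 and matrix proteases and inhibitors 0.82. Switching genes had 0.54 there, TGF-β response -0.13, glycolysis and hypoxia 0.07, dissociation -0.63, mitochondrial 0.17 and haemoglobin 7.18.

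Contractile genes had a median of -1.67 over 13 members in endothelial cells, with Myh11 14.6-fold (10.2 to 21.6) and Myl9 2.72-fold (2.36 to 3.14) lower. Few cells carried the lymphatic part of these counts: 10 of the 29 PBS lymphatic endothelial cells held 1332 of the 1363 Acta2 UMIs of that class. In the shared clusters, without lymphatic cells, the median was -1.58, while the blood endothelial cluster found in the LCWE library lay 1.36 above the LCWE cells of the shared clusters. In blood endothelial cells alone the median was -0.05, Myl9 was higher, with a log2 ratio of 0.41, and Acta2 was at 1288 CPM (1247 to 1329) in the LCWE pool against 432 CPM (401 to 465) in the PBS pool. Here too a few cells weighed heavily, since 10 of the 239 LCWE cells held 1754 of the 3828 Acta2 UMIs, and 49.4% of the LCWE cells had an Acta2 UMI against 85.3% of the PBS cells.

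Smooth muscle cells could be compared with 93 LCWE and 4141 PBS cells, but their make-up differed. A cluster made here (resolution 0.5), led by Olfr558, Nrip2 and the pericyte marker Higd1b, held 37 LCWE and 82 PBS cells. Of these, 99.2% were named smooth muscle cells. The ratios below cannot tell that difference in make-up from a change within cells. Classes were named by expression, with the transitional class apart, so a small contractile difference is partly built in. Contractile genes, which define this cell type, differed little: the list had a median of -0.23 over 14 members, with Acta2 (chromosome 19, 34241090 to 34255590) 1.21-fold (1.2 to 1.23) lower and Tagln 1.16-fold (1.14 to 1.18) lower, while Des and Actg2 were 2.07-fold (1.92 to 2.22) and 2.09-fold (1.92 to 2.27) higher. The switching list was higher with a median of 3.12 over 13 members, 9 of them at least 2-fold: Spp1, osteopontin, was 2452-fold (1664 to 3772) higher, Timp1 85.2-fold (75.5 to 96.2) and Thbs1 20.5-fold (18.9 to 22.3). The matrix list had a median of -0.25 over 16 members, with Postn 2.88-fold (2.62 to 3.16), Sparc 1.78-fold (1.73 to 1.83) and Eln 1.26-fold (1.22 to 1.3) lower (Eln had a log2 ratio of 0.31 with clusters made here), and proteases and inhibitors 1.51 over 10, with Mmp3 136-fold (106 to 176) higher. Chemokines had a median of 4.79 over 13 members, with Cxcl1 20.3-fold (17.6 to 23.3) and Ccl5 206-fold (162 to 266) higher, NF-κB targets 1.26 over 10, and the type I interferon list 4.09 over 9, with Isg15 14.3-fold (12 to 16.9) and Ifit1 27.3-fold (20.4 to 36.4) higher. Transcripts of leukocytes were higher by as much in the same cells: T cell markers had a median of 8.19, macrophage markers 8.14 and class II genes 7.22, with Cd74 at 534 against 3.59 CPM. Ccl5 was at 3.12 UMIs per LCWE smooth muscle cell and 24.7 per LCWE lymphocyte. The TGF-β response list had a median of 0.13, mitochondrial genes 0.24, haemoglobin 4.80 and dissociation genes 0.06, with Hspa1a 2.03-fold (1.88 to 2.19) higher and Fos 1.71-fold (1.64 to 1.78) lower. With the filter on mitochondrial UMIs, the mitochondrial and dissociation medians turned negative.

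The transitional class, present in the LCWE library alone, lay between smooth muscle cells and fibroblasts of that library in contractile genes. Against LCWE smooth muscle cells its contractile list had a median log2 ratio of -2.13, with 13 of 14 members at least 2-fold lower, its matrix list 1.26, with 10 of 16 members higher, and its switching list 1.82, with 7 of 13 higher. Against LCWE fibroblasts the contractile list was higher, with a median of 5.81 and all 14 members at least 2-fold higher, the switching list had a median of 1.93, with 7 of 13 members higher and 3 lower (Ly6a, Klf4 and Mmp2), and the matrix list 0.05. The authors named the class by its expression, so these values describe it and are not independent evidence. With the transitional cells added to the smooth muscle cells, the contractile median of LCWE over PBS was -1.43 and the matrix median 0.72, and Des, Sparc, Eln and Hspa1a had log2 ratios of -0.86, 0.09, 0.88 and -1.08.

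In T, NK and innate lymphoid cells, compared with 2198 LCWE and 75 PBS cells, regulatory T cell genes were higher in the LCWE pool and cytotoxic genes lower. The regulatory list had a median of 1.83 over 5 members, with Ikzf2 8.07-fold (4.71 to 15.2) and Ctla4 5.05-fold (2.88 to 9.79) higher, and Foxp3, the defining transcription factor, had 272 against 0 UMIs, at least 3.55-fold higher. With cells thinned to an equal depth, the Foxp3 UMIs left gave no call. Cells of the regulatory and activated CD4 class were 13.4% (12 to 14.9) of the LCWE and 14.7% (7.56 to 24.7) of the PBS lymphocytes. Of the Ikzf2 UMIs, 1012 lay in the LCWE cells named NKT, at 704 CPM, a class absent from PBS. The cytotoxic list had a median of -0.66 over 10 members, with the granzyme genes Gzma and Gzmb 4.41-fold (4.21 to 4.62) and 3.44-fold (3.04 to 3.87) lower, Prf1 3.88-fold (2.26 to 6.32) and Ccl5 1.55-fold (1.49 to 1.6) lower. The naive list had a median of 0.29 over 6 members, with Tcf7 1.75-fold (1.35 to 2.31) and Il7r 1.61-fold (1.23 to 2.14) higher, and the list of exhausted or activated T cells 0.34 over 6, with Pdcd1, which encodes PD-1, 4.07-fold (1.86 to 11.1) higher. Type I interferon genes had a median of 0.51 over 11 members, interferon gamma response genes 0.39 over 9, and cycling genes -0.86 over 10. The make-up of the class differed between the libraries, since NK cells were 16 of its 75 PBS cells and 281 of its 2198 LCWE cells. Contractile transcripts, which lymphocytes should lack, had a median of -2.91 with Acta2 8.91-fold (7.31 to 10.8) lower, haemoglobin 5.08, dissociation genes -0.33 and mitochondrial genes -0.04. The median log2 ratio over all measured genes of the class was 0.09 in endothelial cells, 0.04 in fibroblasts, 0.12 in smooth muscle cells and -0.19 in T, NK and innate lymphoid cells.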

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

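The 3 tests of the smooth muscle share were chosen only after its result was seen, and the tests of free RNA and of lymph node tissue before. Added after were the ends of the intervals for lymph node tissue and the split of endothelial cells for free RNA.

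The interferon gamma response list had opposite directions in 2 cell types of the same pools, with a median log2 ratio of 1.10 in fibroblasts and -0.81 in endothelial cells. In clusters shared by both libraries the medians were 0.02, with 0 of 9 members 2-fold different, and -0.61, so the opposite direction was absent there. With 1 library per group the difference between the cell types was not tested. The numbering of the cells shows a second point: the highest cell number is 9927 in the LCWE library and 7222 in the PBS library, and the deposited table does not list 48.7% of the LCWE numbers and 25.4% of the PBS numbers. The files hold no counts for these numbers, so what they were is unknown.

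Smooth muscle cells made up 1.83% of the LCWE library and 76.9% of the PBS library. Dilution by leukocytes would leave the ratio of smooth muscle cells to fibroblasts plus endothelial cells alike, but that ratio, LCWE over PBS, was 0.0219 (0.0174 to 0.0274). With the transitional and proliferating stromal cells added it was 0.098 (0.0859 to 0.112), which argues against renaming as the whole cause. Free contractile over free fibroblast transcripts in lymphocytes, LCWE over PBS, was 0.149 (0.123 to 0.182). That argues against smooth muscle cells caught and then missing from the table as the whole cause. It cannot exclude that a part of them was caught and left out, since 48.7% of the LCWE cell numbers are unlisted. Loss of smooth muscle cells in the vasculitis and a lower release of them from LCWE tissue by the enzymes both stay open, and neither was tested.

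Transcripts of other cell types differed in fibroblasts and endothelial cells, where free RNA might be the source. In the PBS library, contractile genes had 1.73 times as many UMIs per cell in fibroblasts as in lymphocytes (median over members, quartiles 1.02 to 2.27), between the limits set in advance, so free RNA cannot be told apart from expression there. In endothelial cells the value was 4.5 (4.02 to 6.81), but it was uneven. The 29 PBS lymphatic cells had 25.9 (19.8 to 35.1), which argues against free RNA alone there, while doublets or attached cells stay open. The 217 blood endothelial cells had 1.5 (0.922 to 4.49), at the limit under which free RNA fits, so free RNA stays open for most of the class. For class II genes in the LCWE library the values were 2.2 (1.98 to 2.6) in fibroblasts and 2.89 (2.65 to 3.23) in endothelial cells, both between the limits, so free RNA from antigen-presenting cells cannot be told apart from expression. Expression of class II genes by the stromal cells stays open as the biological explanation, untested. The interferon gamma list was 1.10 in fibroblasts, where class II was 5.58, and -0.81 in endothelial cells, where class II was 3.25, so a link to interferon gamma is left open.

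Lymphocytes were 43.2% of the LCWE library with B cells counted apart, and lymph nodes lie beside the abdominal aorta. Of 6 genes of lymph node stroma, 1 reached 1 UMI per 10 cells and 10 times the PBS level: Glycam1 in endothelial cells. Ccl19 had 307 and 295 UMIs in LCWE and PBS fibroblasts, and Madcam1 3 and 0 UMIs in endothelial cells, but 2 genes of fibroblasts missed 1 limit each: Cxcl13 at 9.44 times (8.19 to 10.9) the PBS level, and Ccl21a at 0.0689 UMIs per cell and 12.0 times. At the upper ends of the intervals 2 genes reach both limits, so lymph node tissue cannot be told apart from recruitment of lymphocytes to the inflamed wall or lymphoid aggregates around it, which were not tested.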

How the results depend on the processing

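The comparisons of blood endothelial cells, shared clusters and the transitional class, and the filter on the shares of a gene's UMIs, were chosen only after the data were seen. Across the alternatives, without that of Scrublet, 443 of 465 recomputed list medians stayed within the interval of their members and 22 moved beyond it, 102 of 110 shares stayed within their interval, and of 946 gene ratios 536 stayed, 391 moved and 19 changed sign, 1 of them (Foxp3) a bound against the floor. The intervals of abundant genes are narrow, so small shifts count as moved. Those over list members are wide, so a median can change sign and still count as stayed. The endothelial quiescence median did so, at 0.47 in the shared clusters. The cause was not tested for the values below, unless stated.

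With clusters made here (resolution 0.5), the LCWE share of fibroblasts was 3.89%, because the cluster of 618 LCWE cells that holds most of them took no name from the markers. Monocytes, macrophages and dendritic cells were 20.2% in LCWE and 0.631% in PBS, and T, NK and innate lymphoid cells 41.7% in LCWE. The clusters that took the fibroblast name were the shared ones, so their fibroblast ratios repeat the shared-cluster comparison and are no separate check. At resolution 1.0 the markers named LCWE-only clusters of 377 and 246 cells as fibroblasts. At resolution 0.5 the log2 ratios that turned in fibroblasts were Cxcl14 -0.43, Ifit1 -0.38, and Irf7 -0.42, and in smooth muscle cells Eln 0.31. The log2 ratio of Gbp3 in Fibroblast cells was -0.00087.

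With the filter on mitochondrial UMIs, which left out 211 LCWE and 383 PBS cells, the LCWE share was 1.25% for smooth muscle cells and 70.7% for leukocytes, and fibroblasts were 55% of the LCWE non-immune cells. In smooth muscle cells the dissociation list had a median of -0.30, and the median log2 ratio of mitochondrial in VSMC was -0.080. Of the Il1b UMIs, 28.6% lay in the other myeloid cells and 61.8% in monocytes, macrophages and dendritic cells.

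In blood endothelial cells alone the contractile median was -0.055, matrix 0.18 and haemoglobin 6.21, and Myl9 turned to 0.41. In the shared endothelial clusters, without lymphatic cells, chemokines had 0.12, glycolysis and hypoxia 0.068, cycling 0.33 and haemoglobin 7.18, and Thbs1 turned to -2.76, Vwf to 0.11 and Klf2 to 0.27. In the shared fibroblast clusters, which leave out 615 LCWE cells, chemokines had 0.14, type I interferon 0.045, interferon gamma 0.018 and haemoglobin 4.82, and Cxcl14 turned to -0.43, Ifit1 to -0.38 and Irf7 to -0.41.

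With cells thinned to 1500 UMIs, Klf2 in endothelial cells turned to 0.089 and Gsdmd in fibroblasts to -0.058. For Foxp3 in T, NK and innate lymphoid cells, with 0 PBS UMIs, thinning left a bound of at least -0.15 on the log2 scale against the floor, which gives no direction. With the mean over cells, the cycling median of T, NK and innate lymphoid cells was -0.35, and in smooth muscle cells contractile genes had -0.39 and type I interferon genes 5.49. TMM factors, which shift smooth muscle ratios by -0.11 and those of T, NK and innate lymphoid cells by 0.15, gave the contractile list -0.34 in smooth muscle cells.

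With the transitional class added to smooth muscle cells, contractile genes had -1.43, matrix 0.72, dissociation -0.59, mitochondrial -0.32 and haemoglobin 4.35, and Des turned to -0.86, Sparc to 0.094, Eln to 0.88 and Hspa1a to -1.08. With the composition of the PBS library, whole-library log2 ratios were 4.24 for Il1b, 4.26 for Nlrp3, 3.89 for Il1rn and -2.43 for Nlrp1b, as the construction removes the added leukocytes.

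Leaving out Scrublet doublets removed 1 cell and so says little. Not run were 2 alternatives: the use of all barcodes, since the files list the annotated cells alone, and the use of the authors' normalized values, since the joint matrix holds raw counts. Depth limits genes with few UMIs most in the 75 PBS lymphoid cells and the 93 LCWE smooth muscle cells.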

Other observations

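The test of the granulocyte class was chosen only after the result was seen, and the sex test before.

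The cells that the authors named eosinophils held the most Il1b and Nlrp3 UMIs per cell. A hypothesis is that the class may hold neutrophils. Its 142 LCWE cells had 34729 UMIs of the neutrophil markers S100a8, S100a9, Csf3r, Cxcr2 and Retnlg. The eosinophil genes Siglecf, Ccr3, Epx, Prg2 and Il5ra had 43 UMIs there, which gives a ratio of 808. That ratio does not single out neutrophils, since Mono1 monocytes had 792 and 1 UMIs for the same genes. Of the 43 UMIs, 41 were of Siglecf, and Epx, Prg2 and Il5ra had 0 UMIs. Siglecf was at 60.1 CPM, against 5.46 in the class named neutrophils. The class named neutrophils had 118089 and 4 UMIs for the same genes, and more S100a8 per cell, 908 against 111 UMIs. Per cell, Csf3r was at 4.24 UMIs in the class named neutrophils and 5.44 in the class named eosinophils, and Cxcr2 at 3.13 and 2.82. With clusters made here (resolution 0.5), a cluster of 203 LCWE and 5 PBS cells took the neutrophil name. Of its cells, 97.6% were of the broad class that holds both. Free RNA, doublets or attached cells may add neutrophil transcripts to other classes, but Mono1 monocytes had 1.25 UMIs of S100a8 per cell. If the hypothesis holds, part or all of the 23.4% of the library's Il1b UMIs that lay in this class would belong to neutrophils.

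The 318 LCWE cells named NKT had 7 UMIs of Zbtb16, the transcription factor of invariant NKT cells, and 487 UMIs of Cd3e. They expressed Ikzf2 at 704 CPM, Xcl1 at 986 CPM, and the NK receptor genes Klra1 at 213 CPM and Klra7 at 334 CPM.

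Within the LCWE library, the fibroblasts of the cluster absent from PBS had higher list medians than the LCWE fibroblasts of the shared clusters for inflammatory myeloid genes (1.95), type I interferon (1.87), class II (1.62), chemokines (1.31) and interferon gamma (0.99), with complement at 0.31 and matrix at 0.05. The blood endothelial cells of their LCWE cluster had higher TGF-β response (1.68) and cycling (1.36) medians and lower quiescence (-0.68), with contractile (1.36), class II (1.17) and inflammatory myeloid (1.09) medians higher too. Myeloid, class II and contractile genes are tied to other cell types, so transcripts caught from such cells are not excluded as a part of these differences. The clusters are defined by expression, so such differences are partly built in.

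Of the 75 PBS cells named T, NK or innate lymphoid, 1 held 1190.0 of the 1216 UMIs of the mast cell genes Cpa3, Mcpt4, Tpsb2 and Cma1. Pools of different sex are argued against: summed Y-linked genes were 1.2 times (1.17 to 1.24) as abundant in the LCWE library, and Xist had 5 and 10 UMIs.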
